A study of Rattus norvegicus with 48 samples.

How the data were processed

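Gene expression was measured in liver biopsies of 48 rats on Affymetrix arrays, 1 array per animal, in 5 groups taken from the sample labels. The deposited values are log2 expression values per probe set, which the authors made with RMA in Affymetrix Expression Console; RMA corrects for background, normalizes probe quantiles and summarises probes. The labels state no version, no filter and no day or batch of hybridization, so no batch could be entered in the model. All 29215 probe sets had a value in every array. A gene symbol from the platform annotation was used where a probe set had exactly 1 (15310 probe sets); 323 had several and 13582 had none here. For each of the 14506 genes the probe set with the highest mean over all arrays was used, and no filter on dim genes was applied.

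Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values and all 5 groups in 1 fit (43 residual degrees of freedom), two-sided, without covariates. Benjamini-Hochberg adjusted p values were taken over the genes of a comparison, and 0.05 was the threshold. The 10 pairwise comparisons and the interaction of the interventions were tested; 4 were set as main comparisons: IRI with sham, and each intervention group with IRI. IRI is a shared control of the latter 3. No paired analysis was possible because the groups share no animal numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

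The groups, comparisons, 31 gene lists and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry; fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. Counts adjusted over the list alone apply the Benjamini-Hochberg procedure to the list's members. The rule for named genes took the 10 largest rises and 10 largest falls past the threshold in a main comparison, or the 10 smallest p values where fewer than 10 genes passed, then the 3 largest of each in other comparisons, and the 4 members of smallest p of a list; predicted loci and small RNA genes were skipped (4 in IPO against IRI, 2 and 3 in IPC and IPO against sham). The text gives a selection of these genes. Kdsr and the 8 other genes called with a covariate in IPC+IPO against IRI, and the genes of the clock index, were singled out after their values were seen unless the rule named them.

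Alternatives were: only the groups compared, a trended and robust variance model, array weights, leaving out the dimmest 33.3% of genes, all probe sets, the probe set of largest variance, median centring, renewed quantile normalization, a 1.5-fold minimum, an adjusted p under 0.01, and leaving out each array in turn. After the data were seen, array spread as a covariate, leaving out the 14 arrays of lowest spread and removal of each gene's slope on spread within groups were added. Differences in spread and in clock genes were tested with permutations, single outlying values with Dixon's ratio, and counts were repeated for 100 draws of other splits of the arrays.

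The correlation of the IPC and IPO differences used odd and even numbered IRI animals as separate controls, in both orders, and 100 simulated draws in which the residuals of the IRI, IPC and IPO arrays were reshuffled. The pipeline was tested on simulated data of 14506 genes with 100 genes changed per comparison and size: limma found 62% of genes changed 1.5-fold and 97% of those changed 2-fold in IRI against sham, 81% and 93% in IPC against IRI, 74% and 98% in IPO against IRI, and 76% and 99% in IPC+IPO against IRI. The simulated noise was independent between genes, unlike the array spread seen here. Probe sets with no or several symbols entered no gene count.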

Results

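Liver biopsies from 48 male Wistar rats were profiled on Affymetrix arrays, 1 array per rat, and per the labels the rats are separate animals. The sham group held 8 rats without ischemia. The ischemia and reperfusion group (IRI) held 10 rats whose whole liver was made ischemic for 30 min and then reperfused for 30 min. The preconditioned group (IPC) held 10 rats that had 10 min of ischemia and 10 min of reperfusion before the same insult. The postconditioned group (IPO) held 10 rats in which reperfusion began with 3 cycles of 30 sec of flow and 30 sec of ischemia. The IPC+IPO group held 10 rats with both interventions. The number of arrays limits the precision of every value given here.

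The arrays differed in how widely their values were spread. Array medians lay between 5.78 and 5.92 on the log2 scale. The standard deviation of the log2 values over the 14506 genes of an array, called its spread here, ran from 1.5 to 1.97. Mean spread was 1.72 ± 0.134 (SD) in sham, 1.77 ± 0.111 in IRI, 1.85 ± 0.083 in IPC, 1.91 ± 0.065 in IPO and 1.86 ± 0.153 in IPC+IPO. It was higher in IPO than in IRI by 0.14 (two-sided permutation p = 0.00252, adjusted over 10 comparisons 0.0158) and than in sham by 0.185 (permutation p = 0.00317, adjusted 0.0158); none of the other 8 comparisons passed. The first principal component held 43.2% of the variance and followed spread over the 48 arrays (Pearson r = 0.975, Spearman rho = 0.981, each with permutation p = 1e-05, the smallest these permutations can give). Pearson r was 0.98 without the 2 arrays farthest from the median spread and 0.97 within groups.

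**Figure D1:**
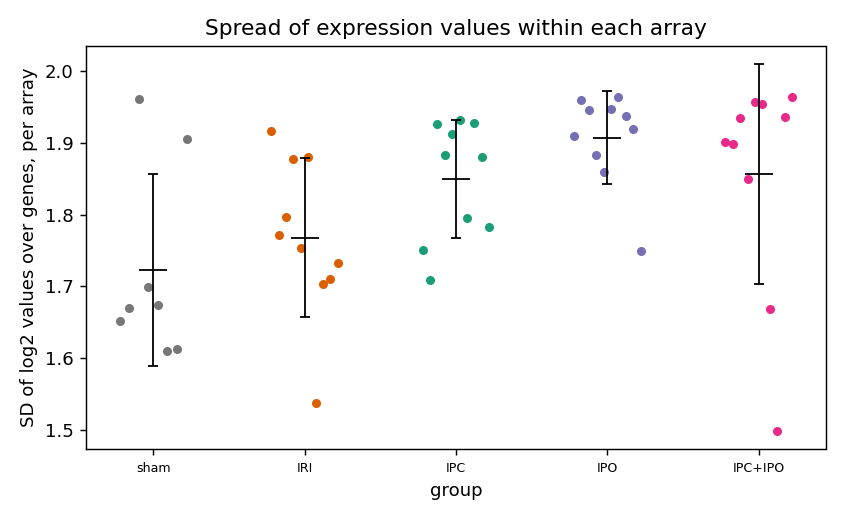
The standard deviation of the log2 values over genes (vertical axis, log2 units) of each array by group; points are animals, bars the mean and SD. The means run from 1.72 in sham to 1.91 in IPO, and the lowest array, at 1.5, is in the IPC+IPO group.

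The comparison of IRI with sham asked what ischemia and short reperfusion changed in the liver. In IRI livers, Junb (probe set 10806585), a subunit of the AP-1 transcription factor, was at 8.46 ± 0.61 (SD, n = 10) on the log2 scale against 7.10 ± 0.64 (SD, n = 8) in sham, a 2.57-fold rise, with 8 of the IRI animals above every sham animal. Without IRI animal 5, its highest value, Junb stood at 1.20 ± 0.31 (SE) and was not called (adjusted p = 0.0741). Enzymes of the mevalonate and cholesterol pathway rose, Fdps 1.97-fold and Tm7sf2 2.19-fold, as did the antioxidant enzyme Gpx1 (1.7-fold), the ferritin light chain gene Ftl1 (1.57-fold) and Ninj1 (2-fold), which codes for a protein of plasma membrane rupture. Without the 14 arrays of lowest spread, a fit chosen after the data were seen that keeps 2 sham arrays, none of these passed: Tm7sf2 and Ftl1 turned to -0.177 and -0.132, and Fdps, Gpx1, Ninj1 and Junb stood at 0.009, 0.107, 0.107 and 0.517. Of the ribosomal protein genes, Rpl13 rose by 0.63 ± 0.11 (SE) on the log2 scale and Rplp0 by 0.75 ± 0.17. Genes that fell were Fkbp5, a glucocorticoid-induced co-chaperone, by 0.77 ± 0.18, Glg1 by 0.65 ± 0.16, Lsm12 by 0.50 ± 0.09 and the stellate cell receptor gene Pdgfra by 0.46 ± 0.10. In all, limma called 35 of the 14506 genes at an adjusted p under 0.05, 25 higher and 10 lower in IRI, with 1662 at an unadjusted p under 0.05.

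By gene list, camera at the preset correlation gave ribosomal proteins its smallest p in IRI against sham, while fry called oxidative stress genes alone. Camera at that correlation also called a median of 6 lists over other splits of the same arrays. Of the 67 cytosolic ribosomal protein genes measured, 4 rose (Rpl13, Rpl23, Rplp0 and Rpsa), none fell and 63 were not past the threshold; 29 rose when adjusted over the list alone. The median difference was 0.25 (camera adjusted p = 1.5e-15, adjusted p = 0.479 with an estimated correlation). Among 34 immediate-early genes Junb rose, and 8 rose adjusted over the list alone; Gadd45a differed by 1.36 ± 0.39 (adjusted p = 0.0952) and Gadd45g by 1.23 ± 0.31 (adjusted p = 0.0582). This list had a median of 0.42 (camera adjusted p = 2.18e-06, adjusted p = 0.479 with an estimated correlation). Of 27 oxidative stress genes, Gpx1 and Ftl1 rose and 6 did adjusted over the list alone. Its median was 0.27 (camera adjusted p = 4.57e-06, adjusted p = 0.479 with an estimated correlation, fry adjusted p = 0.0256). Among 19 lipid and cholesterol synthesis genes Fdps rose and 6 did adjusted over the list alone, with Cyp51 at 0.57 ± 0.15 and Insig1 at 0.78 ± 0.24. Its median was 0.38 (camera adjusted p = 1.55e-05, adjusted p = 0.479 with an estimated correlation). Camera also called 15 MAPK feedback regulators (median 0.28, adjusted p = 0.0155) and 34 genes of respiratory chain complex I (median 0.21, adjusted p = 0.000307), where no gene passed over all genes; with an estimated correlation their adjusted p values were 0.626 and 0.972. The medians of these 6 lists were 0.23, 0.36, 0.20, 0.27, 0.30 and 0.18 with array spread as a covariate, where camera did not call the last 2 (adjusted p = 0.0716 each). With the covariate and an estimated correlation together camera called none of them.

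Camera at the preset correlation called 2 marker lists in IRI against sham. Of the 11 erythroid and platelet markers 0 passed over all genes; they had a median difference of 0.36 from sham with all 11 above 0, Hba-a3 at 0.93 ± 0.27 and Hbb at 0.74 ± 0.26, and 3 rose adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.479 with an estimated correlation). The 20 stellate and mesenchymal markers had a median of -0.14; Pdgfra alone fell over all genes, and 5 fell adjusted over the list alone, with Col1a2 at -0.41 ± 0.12 (camera adjusted p = 0.00013, adjusted p = 0.479 with an estimated correlation). Camera called both with array spread as a covariate, at medians of 0.36 and -0.18, but neither when an estimated correlation was used too (adjusted p = 0.777 and 0.404). As deposited, camera did not call the other marker lists, among them hepatocyte, neutrophil and Kupffer cell markers, with medians of 0.02, 0.03 and 0.03. The count of genes rested on single arrays: it lay between 1 and 15 without any of IRI animals 3 to 6, 9 or 10 or sham animals 41, 42 or 44 to 47. It was 54 and 56 without IRI animals 7 and 1, 219 without sham animal 43 and 324 without sham animal 48. With array spread as a covariate, chosen after the data were seen, 854 genes passed (430 higher, 424 lower, all 35 among them), against 2 with arrays centred on their medians (1 higher, 1 lower) and 259 after renewed quantile normalization (138 higher, 121 lower). The count was 0 in a fit of these groups alone and 3 without the 14 arrays of lowest spread (0 of the 35 among them).

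**Figure D2:**
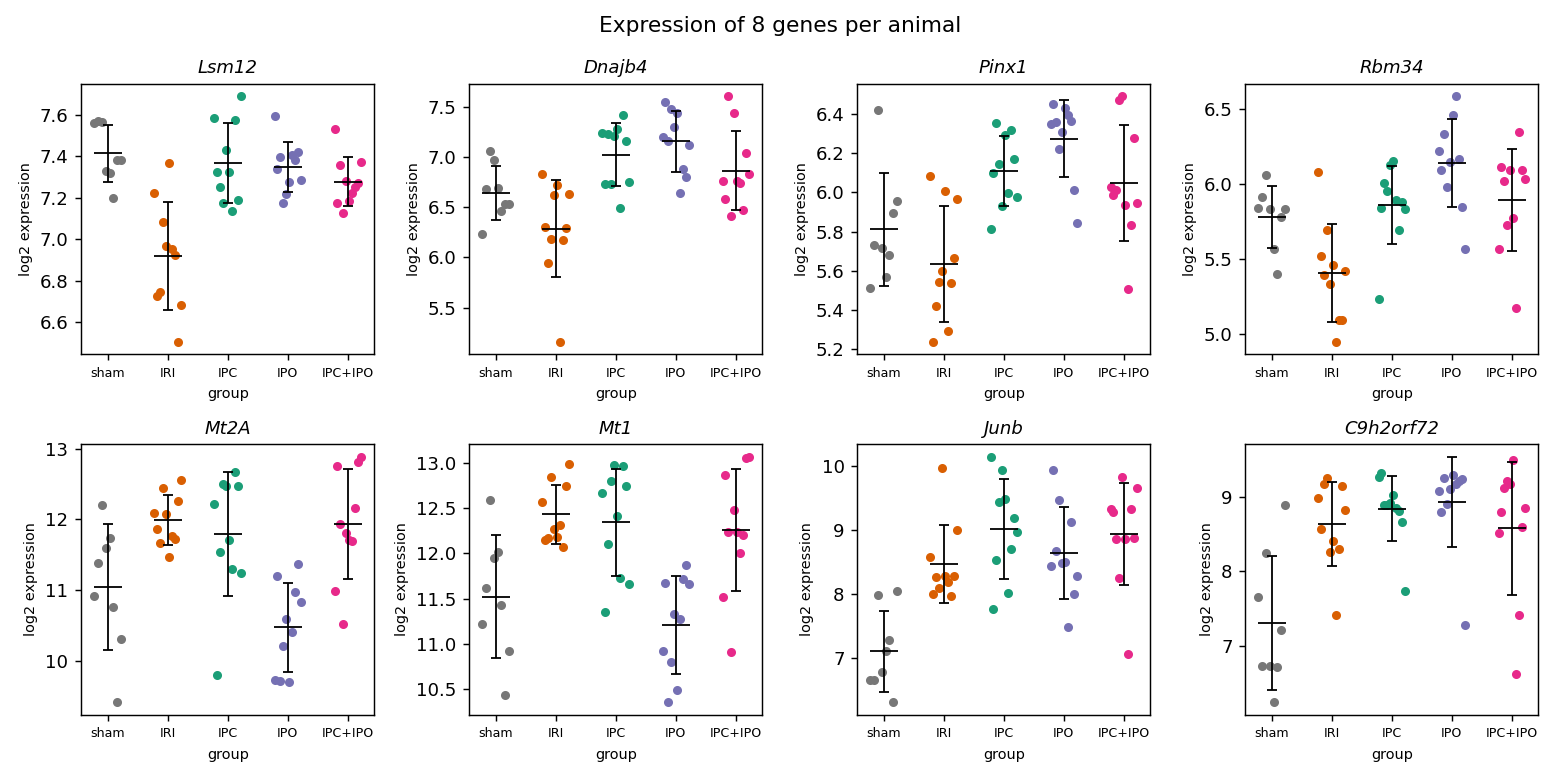
Log2 expression (vertical axes) of 8 genes by group: the 6 with the smallest p in a test over the 4 ischemic groups and the 2 with the largest rise in IRI against sham; points are animals, bars the mean and SD. Mt2A and Mt1 differ by -1.52 and -1.22 between IPO and IRI.

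Comparing IPC with IRI asked what preconditioning changed in livers with the same 30 min of ischemia and 30 min of reperfusion. The preconditioned livers had a further 10 min of ischemia and 10 min of reperfusion before these. The comparison cannot tell an effect on the later insult apart from that of the added ischemia and time. Preconditioned livers had more mRNA of Plat, the tissue plasminogen activator, which rose by 0.56 ± 0.11 (SE) on the log2 scale (1.47-fold, adjusted p = 0.0472), and of Lsm12, which rose by 0.45 ± 0.08 (1.37-fold, adjusted p = 0.0313). Apln, which codes for the vasoactive peptide apelin, fell by 0.34 ± 0.07 (adjusted p = 0.0475), and the olfactory receptor gene Or4c58 fell by 0.48 ± 0.10 (adjusted p = 0.0472). These 4 genes, 2 higher and 2 lower, were all that limma called, with 2799 at an unadjusted p under 0.05. Next in rank stood the lipid droplet gene Plin2 at 1.18 ± 0.25 (2.26-fold), the chaperone gene Dnajb4 at 0.74 ± 0.16 and the MHC class II gene RT1-Bb at 0.84 ± 0.18, each with an adjusted p of 0.0556, and then Ushbp1, Rasl10a and Jund. Dnajb4 stood at 0.61 ± 0.14 without IRI animal 7, its lowest value (adjusted p = 0.176).

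Immediate-early genes led the lists in IPC against IRI. Of 34 measured, 0 passed over all genes and 16 rose adjusted over the list alone; the median was 0.50, and 31 were above 0. Zfp36, an mRNA decay factor, stood at 1.39 ± 0.36, the transcription factors Egr1 and Jund at 1.27 ± 0.35 and 0.93 ± 0.22. Camera gave the list an adjusted p of 2.08e-09, with adjusted p = 0.33 with an estimated correlation. Of 19 fatty acid oxidation and ketogenesis genes, 0 passed over all genes and 7 rose adjusted over the list alone, with Pdk4, a brake on glucose oxidation, at 1.32 ± 0.33 and the hormone gene Fgf21 at 1.20 ± 0.34. Its median was 0.34 (camera adjusted p = 1.96e-05, adjusted p = 0.33 with an estimated correlation). Of 22 vasoactive and adenosine pathway genes Plat rose and 8 did adjusted over the list alone, with the adenosine receptor gene Adora2a at 0.42 ± 0.12 and Thbd at 0.40 ± 0.13. Its median was 0.13 (camera adjusted p = 0.00997, adjusted p = 0.33 with an estimated correlation). Of 18 glucocorticoid-induced genes 5 rose adjusted over the list alone. Its median was 0.37 (camera adjusted p = 0.000327, adjusted p = 0.33 with an estimated correlation). The 67 ribosomal protein genes had a median of -0.14 with none past either threshold, Rps14 at -0.74 ± 0.21 (camera adjusted p = 0.000128, adjusted p = 0.519 with an estimated correlation). For these 5 lists the medians with array spread as a covariate were 0.39, 0.14, 0.09, 0.21 and -0.19. Camera called each at the preset correlation, and none with an estimated one (adjusted p = 0.282, 0.282, 0.282, 0.282 and 0.353). In that fit 8, 4, 4 and 1 members rose and 2 ribosomal protein genes fell adjusted over the list alone.

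Kupffer cell and macrophage markers had a median of 0.29 in IPC against IRI, and 6 of 18 rose adjusted over the list alone, with Cd5l at 0.79 ± 0.24 and Marco at 0.69 ± 0.24 (camera adjusted p = 8.08e-05, adjusted p = 0.344 with an estimated correlation). Of 20 stellate and mesenchymal markers 4 rose adjusted over the list alone, with Vim at 0.64 ± 0.20. Its median was 0.16 (camera adjusted p = 0.00241, adjusted p = 0.344 with an estimated correlation). The 11 erythroid and platelet markers had a median of -0.31 (camera adjusted p = 0.00415, adjusted p = 0.344 with an estimated correlation), and the 18 neutrophil markers one of -0.11 (camera adjusted p = 0.0211, adjusted p = 0.458 with an estimated correlation). The Kupffer, stellate, erythroid and neutrophil medians were 0.12, 0.12, -0.31 and 0.014 with array spread as a covariate; camera did not call the last (adjusted p = 0.75), and 0 members passed adjusted over the list alone. In all, camera called 21 of the 31 lists as deposited and none with an estimated correlation; the 12 not given here had medians between 0.11 and 0.32. The 4 genes were lost with spread as a covariate, in a fit of these groups alone and with a trended, robust variance model (0 genes each). Without the 14 arrays of lowest spread 3 genes passed, 0 of the 4 among them, while array weights gave 568. The count was 252 without IRI animal 1, 8 and 7 without IPC animals 17 and 20, and 0 or 1 without IRI animals 2, 5 and 7 to 9 or IPC animals 11, 12, 14 to 16, 18 and 19.

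Postconditioning was compared with IRI, which had the same 30 min of ischemia but not the 3 short cycles at reperfusion. In IPO livers the metallothionein genes Mt2A and Mt1, which bind zinc and copper, fell by 1.52 ± 0.31 (SE) and 1.22 ± 0.24 on the log2 scale, and for each gene all 10 IPO animals lay below every IRI animal. Mt2A was at 10.47 ± 0.63 (SD, n = 10) in IPO and 11.99 ± 0.36 (SD, n = 10) in IRI. In IPC+IPO livers, which had the same cycles, neither gene was called against IRI. There Mt2A ran from 10.516 to 12.887 over animals, against 11.471 to 12.564 in IRI and 9.415 to 12.2 in sham. Clock genes moved apart: Bmal1, Clock and Cry1 rose 2.42-fold, 1.94-fold and 1.52-fold. Dbp, a transcription factor of the clock's output, fell by 1.69 ± 0.51. The taurine transporter gene Slc6a6 rose 3.23-fold, the desaturase gene Scd 2.73-fold and Angptl4, an inhibitor of lipoprotein lipase, 2.43-fold. Hspd1 and Hspb1, chaperone genes, rose 1.92-fold and 2.17-fold. Other large falls were those of Ubd, a ubiquitin-like modifier, by 1.68 ± 0.54, the steroid dehydrogenase gene Hsd17b2 by 1.58 ± 0.39 and the uridine phosphorylase gene Upp2 by 1.25 ± 0.41. Only Mt1 and Mt2A stayed called with array spread as a covariate; Slc6a6, Scd, Angptl4 and Bmal1 were then at 1.08 ± 0.37, 0.96 ± 0.37, 0.77 ± 0.25 and 0.98 ± 0.35, and Dbp, Ubd and Hsd17b2 at -1.53 ± 0.55, -1.74 ± 0.59 and -1.63 ± 0.43.

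Of 20 heat shock chaperones measured, 12 rose in IPO against IRI, 0 fell and 8 were not past the threshold, and 13 rose adjusted over the list alone. Dnajb4 stood at 0.87 ± 0.16, Hspd1 at 0.94 ± 0.19 and Dnaja1 at 0.70 ± 0.15. Its median was 0.58 (camera adjusted p = 2.96e-06, adjusted p = 0.654 with an estimated correlation, fry adjusted p = 0.00385). Of 19 acute phase protein genes 11 rose, 8 did not pass and 13 rose adjusted over the list alone, with the fibrinogen chains Fga and Fgb at 0.39 ± 0.10 and 0.29 ± 0.07. Its median was 0.28 (camera adjusted p = 0.000255, adjusted p = 0.654 with an estimated correlation). Fatty acid oxidation genes rose in 6 of 19 cases, or 11 adjusted over the list alone, with Acadm at 0.53 ± 0.15 and Hadha at 0.60 ± 0.17. Its median was 0.38 (camera adjusted p = 0.00189, adjusted p = 0.654 with an estimated correlation). Of 25 interferon-stimulated genes 6 rose, also adjusted over the list alone, with Rig1 at 0.95 ± 0.22 and Ifi44l at 0.80 ± 0.22. IRI animal 7, whose array had the lowest mean correlation with the others (0.888) and a spread of 1.537, was lowest in Dnajb4, Hspd1 and Rig1. Without it these stood at 0.75 ± 0.14, 0.78 ± 0.17 and 0.75 ± 0.19 (adjusted p = 0.0106, 0.0257 and 0.0397). The median of the interferon list was 0.37 (camera adjusted p = 0.00245, adjusted p = 0.654 with an estimated correlation). Of 21 gluconeogenesis and insulin response genes 6 rose and 9 did adjusted over the list alone, Pygl at 0.67 ± 0.17 and G6pc1 at 0.76 ± 0.20. Its median was 0.34 (camera adjusted p = 0.00413, adjusted p = 0.654 with an estimated correlation). With array spread as a covariate 0 members of these 5 lists passed over all genes, and 5, 0, 0, 0 and 0 did adjusted over the list alone. The medians were then 0.20, 0.12, 0.05, 0.08 and -0.013, with camera adjusted p = 2.99e-08, 0.00519, 0.147, 0.0255 and 0.709. With the covariate and an estimated correlation together camera called none of the lists (adjusted p = 0.149, 0.896, 0.896, 0.896 and 0.948).

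Members of other lists in IPO against IRI were called too. Of 15 clock genes 4 rose and 2 fell, and 5 and 5 did adjusted over the list alone, with a median of -0.20 that camera did not call (adjusted p = 0.92). Of 67 ribosomal protein genes 9 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone, with Rpl36 at -0.52 ± 0.12 and Rps14 at -0.73 ± 0.21. Its median was -0.14 (camera adjusted p = 0.0282, adjusted p = 0.748 with an estimated correlation). Lipid and cholesterol synthesis genes (3 of 19 rose, 3 adjusted over the list alone) and drug and bile acid metabolism genes (4 of 29 rose, 4 adjusted over the list alone) had medians of 0.28 and 0.22. They had camera adjusted p values of 0.0496 and 0.0118, and adjusted p = 0.654 each with an estimated correlation. Under the same covariate the medians were -0.12 for clock genes (2 rose and 5 fell adjusted over the list alone), -0.22 for ribosomal proteins (12 fell so, with camera adjusted p = 1.42e-12), and -0.008 and -0.01 for the latter 2 lists, which camera did not call (adjusted p = 0.912 and 0.858). The call of ribosomal proteins under the covariate was lost with an estimated correlation (camera adjusted p = 0.896). Of 27 oxidative stress genes 5 rose, among them Hmox1 at 0.77 ± 0.20, and 3 fell, Mt1, Mt2A and Abcc4, while 6 rose and 4 fell adjusted over the list alone (median 0.11, or -0.07 with the covariate; camera adjusted p = 0.394). Complex I genes had a median of 0.01 as deposited, -0.138 with the covariate and -0.135 after renewed quantile normalization.

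Cell type markers in IPO against IRI went both ways. Of 21 hepatocyte markers 4 rose, among them Ass1 at 0.68 ± 0.15, and 1 fell (6 and 1 adjusted over the list alone; median 0.13; camera adjusted p = 0.00245, adjusted p = 0.654 with an estimated correlation). Of 18 Kupffer cell and macrophage markers, Cd5l and Cd68 rose by 0.79 ± 0.24 and 0.60 ± 0.21, and 1 rose adjusted over the list alone (median 0.26; camera adjusted p = 0.0195, adjusted p = 0.654 with an estimated correlation). Of 18 neutrophil markers Elane and Defa5 fell by 0.37 ± 0.09 and 0.29 ± 0.09, and 6 fell and 1 rose adjusted over the list alone. Its median was -0.20 (camera adjusted p = 0.0195, adjusted p = 0.654 with an estimated correlation). The hepatocyte, Kupffer and neutrophil medians were 0.01, -0.043 and -0.03 with array spread as a covariate (camera adjusted p = 0.514, 0.858 and 0.912), and 0 members passed adjusted over the list alone. As deposited, camera did not call endothelial, stellate, cholangiocyte, lymphocyte, erythroid or mesothelial markers (medians 0.18, 0.22, -0.12, -0.13, -0.21 and 0.04), although single members passed: 2 endothelial and 3 stellate markers rose, and 1 endothelial, 1 cholangiocyte, 1 lymphocyte and 1 mesothelial marker fell, as did Hbb by 0.67 ± 0.24.

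In all, limma called 3307 genes between IPO and IRI, 1797 higher and 1510 lower, with a median size of 0.42 on the log2 scale; 688 differed at least 1.5-fold and 41 had an adjusted p under 0.01. With array spread as a covariate 2 genes remained, Mt1 and Mt2A, and without the 14 arrays of lowest spread 1077 passed, 787 of them among the 3307. An F test over the 4 ischemic groups together called 10 genes at an adjusted p under 0.05. Between IPO and IRI, arrays centred on their medians gave 2125 higher and 655 lower genes. The count was 395 without IRI animal 7, 1744 and 1771 without IRI animals 8 and 9, 1828, 1994, 1924, 1833 and 2017 without IPO animals 22, 23, 26, 27 and 28, and 5345 without IRI animal 1.

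**Figure D3:**
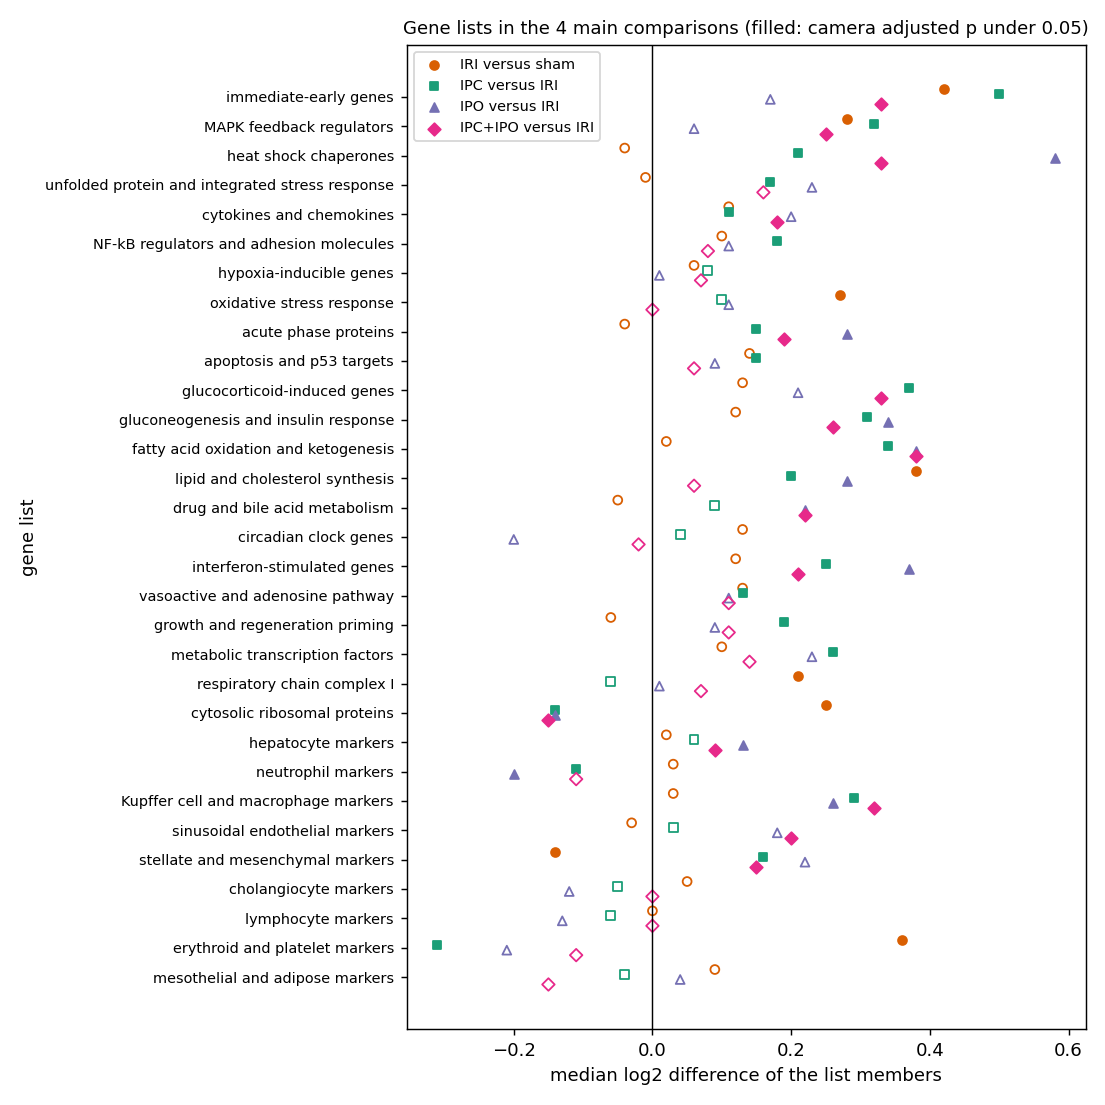
Median log2 difference of the members (horizontal axis) of each of the 31 gene lists (vertical axis) in the 4 main comparisons; filled symbols have a camera adjusted p under 0.05 with the preset correlation, and none does with an estimated one. Heat shock chaperones reach 0.58 in IPO against IRI and immediate-early genes 0.50 in IPC against IRI.

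Livers with both interventions were compared with IRI for the effect of the combination, which includes the added ischemia and time of preconditioning. No gene passed: the smallest adjusted p was 0.0883, for Kdsr, an enzyme of sphingolipid synthesis, at 0.71 ± 0.14 (SE) on the log2 scale, with 9 of the 10 IPC+IPO animals above every IRI animal. The ceramide synthase gene Cers2 stood at 0.96 ± 0.22, the glutaredoxin gene Glrx at 0.97 ± 0.22, the lamin-processing protease gene Zmpste24 at 0.89 ± 0.21 and the endothelial early-response gene Apold1 at 1.21 ± 0.28, each with an adjusted p of 0.0942. Without IRI animal 7 Glrx and Zmpste24 were at 0.81 ± 0.20 and 0.71 ± 0.19 (adjusted p = 0.271 each). At an unadjusted p under 0.05 limma counted 3118 genes. With array spread as a covariate 9 genes passed, and 62 did after renewed quantile normalization, 2 among all probe sets, 4484 with array weights and 601 without the 14 arrays of lowest spread. The count was 1705, 351, 784 and 2 without IPC+IPO animals 38 and 37 and IRI animals 1 and 6.

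Camera called 15 of the 31 lists in IPC+IPO against IRI, and none with an estimated correlation. Of 19 fatty acid oxidation genes 0 passed over all genes and 10 rose adjusted over the list alone, with Cyp4a1 at 0.58 ± 0.17, Hadha at 0.62 ± 0.17 and Angptl4 at 1.03 ± 0.29. Its median was 0.38 (camera adjusted p = 2.08e-06, adjusted p = 0.549 with an estimated correlation). Acute phase genes had 3 of 19 that rose adjusted over the list alone, with Lbp at 0.76 ± 0.21. Its median was 0.19 (camera adjusted p = 1.64e-05, adjusted p = 0.549 with an estimated correlation). Heat shock chaperones had 3 of 20, with Dnaja1 at 0.58 ± 0.15 and Hspd1 at 0.67 ± 0.19 adjusted over the list alone. Its median was 0.33 (camera adjusted p = 0.000118, adjusted p = 0.549 with an estimated correlation). Immediate-early genes had 2 of 34, with Zfp36 at 1.39 ± 0.36 and Nr4a1 at 0.89 ± 0.26. Its median was 0.33 (camera adjusted p = 0.000255, adjusted p = 0.549 with an estimated correlation). The 67 ribosomal protein genes had a median of -0.15, and 9 fell and 1 rose adjusted over the list alone, Rps14 at -0.78 ± 0.21 (camera adjusted p = 0.000387, adjusted p = 0.61 with an estimated correlation). Kupffer cell and macrophage markers had 5 of 18 that rose adjusted over the list alone, with Adgre1 at 0.54 ± 0.17. Its median was 0.32 (camera adjusted p = 8.24e-05, adjusted p = 0.549 with an estimated correlation). Hepatocyte markers had a median of 0.09 (2 of 21 rose adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.559 with an estimated correlation). For these 7 lists the medians with array spread as a covariate were 0.20, 0.11, 0.13, 0.23, -0.21, 0.13 and -0.001, and camera did not call the last (adjusted p = 0.456); 4, 1, 3, 0, 0, 0 and 0 members rose and 10 ribosomal protein genes fell adjusted over the list alone. The other 8 called lists were sinusoidal endothelial markers (median 0.20), stellate markers (0.15), MAPK feedback (0.25), cytokine (0.18), glucocorticoid-induced (0.33), gluconeogenesis (0.26), drug metabolism (0.22) and interferon genes (0.21). With the covariate camera called MAPK feedback, cytokine and glucocorticoid-induced genes among these, but not with an estimated correlation too (adjusted p = 0.595, 0.555 and 0.555).

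Against sham, the 3 intervention groups shared their largest rise. All 3 also had the ischemia and reperfusion of the IRI group, so differences from sham do not separate an intervention from that insult. Atf3, a stress-induced transcription factor, rose 7.59-fold in IPC, 6.18-fold in IPO and 6.33-fold in IPC+IPO. In IPC the chemokine gene Cxcl1 rose 5.37-fold and Gadd45a, a gene of the DNA damage response, 5.19-fold, while the glycolysis regulator Pfkfb1 fell by 1.04 ± 0.22 (SE), the RNase P RNA gene Rpph1 by 1.03 ± 0.28 (0.314 without the 14 arrays of lowest spread, not called) and Fmo1 by 0.97 ± 0.22. In IPO the cytokine signalling inhibitor Socs2 rose 4.31-fold and Slc6a6 4.16-fold, while Ubd fell by 1.61 ± 0.58, Dbp by 1.53 ± 0.54 and Upp2 by 1.26 ± 0.43. In IPC+IPO, Zfp36 rose 4.34-fold and Gadd45a 4.31-fold, while the histone gene H4c14 fell by 0.71 ± 0.20, Krt83 by 0.69 ± 0.14 and Foxd3 by 0.64 ± 0.15. Of 34 immediate-early genes, 22 rose in IPC, 20 in IPO with 1 that fell, and 15 in IPC+IPO. Adjusted over the list alone 26, 21 and 23 rose and 1, 3 and 1 fell (camera adjusted p = 6.67e-18, 8.59e-06 and 4.89e-12, adjusted p = 0.154, 0.576 and 0.432 with an estimated correlation). Lipid and cholesterol synthesis genes rose in 10, 11 and 1 of 19 cases, and in 13, 13 and 9 adjusted over the list alone (camera adjusted p = 4.9e-09, 8.59e-06 and 0.000132, adjusted p = 0.173, 0.576 and 0.432 with an estimated correlation). Under array spread as a covariate 15, 0 and 7 immediate-early and 3, 0 and 0 lipid synthesis genes rose, and 26, 16 and 20 and 6, 2 and 0 did adjusted over the list alone. It took the medians from 0.84, 0.64 and 0.71 to 0.69, 0.45 and 0.55 for immediate-early genes. For lipid synthesis genes they went from 0.64, 0.55 and 0.44 to 0.34, 0.18 and 0.15, the last without a camera call (adjusted p = 0.13). With the covariate and an estimated correlation together camera called neither list in any of these groups. Fry, which does not compare a list with other genes, called both lists in each group as deposited. Its adjusted p values were 8.93e-05, 0.00499 and 0.00293 for immediate-early genes and 0.0012, 0.00283 and 0.0312 for lipid synthesis genes. Fry was not run with the covariate.

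The counts against sham were 955 genes in IPC (812 higher, 143 lower), 3364 in IPO (2238 higher, 1126 lower) and 525 in IPC+IPO (443 higher, 82 lower). With array spread as a covariate they were 275, 0 and 34, of which 132, 0 and 15 were among the genes above, and without the 14 arrays of lowest spread, which left 2 sham arrays, they were 7, 0 and 0. The share of higher genes moved with scaling, from 85% to 73.8% in IPC and from 84.4% to 73.8% in IPC+IPO after renewed quantile normalization, and from 66.5% to 81% in IPO with centred arrays. It was 57.2%, 54% and 55.5% in IPC, IPO and IPC+IPO with array weights, and 50.2% in IPC and 55.9% in IPC+IPO with array spread as a covariate. Without sham animals 43 and 48 the IPC count was 2391 and 1915, and without sham animals 41, 42 and 44 to 47 or IPC animals 13 to 16 and 18 it lay between 293 and 590. For IPO it was 5572 without sham animal 43 and between 1789 and 2027 without sham animals 41, 42 and 45 to 47. For IPC+IPO it was 2432, 1788, 1826 and 2357 without sham animals 43 and 48 and IPC+IPO animals 37 and 38, and between 49 and 217 without any other animal of those groups but IPC+IPO animal 34.

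Between the intervention groups, limma called 0 genes for IPC+IPO against IPC, for IPC+IPO against IPO and for IPO against IPC, with 235, 482 and 589 at an unadjusted p under 0.05. The 4 ischemic groups form a factorial design, and 0 genes had an interaction of the interventions (2942 at an unadjusted p under 0.05). Array weights gave 0, 12, 82 and 189 genes for these tests, and renewed quantile normalization 1 for IPC+IPO against IPC. Leaving out 1 array raised a count from 0 in 3 cases, to 2 without IPC+IPO animal 34 for IPC+IPO against IPO, to 2 without IPC animal 12 for IPO against IPC and to 8 without IRI animal 1 for the interaction. On simulated arrays with independent noise, limma found 48% of genes given a 1.5-fold interaction and 80% of those given a 2-fold one.

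Across genes, which are not independent replicates, the differences of IPC from IRI and of IPO from IRI were compared with separate IRI animals as controls. Pearson r was 0.685, against a simulated mean of -0.055 and a highest value of 0.447 over 100 draws without effects (one-sided simulated p = 0.01, the smallest these draws can give). The covariance was 0.0496 against a simulated -0.00168. With all 10 IRI animals as controls of both, r was 0.886 and its simulated mean 0.455, and the covariance was 0.0595 against a simulated 0.00737. With each gene's slope on array spread removed, r was 0.383 and the covariance 0.0115, and the highest simulated r was 0.498 (one-sided simulated p = 0.04). The planned slope of each intervention's difference on the change from sham to IRI, with the IRI animals split, could not be computed, since 0 genes passed in either part. With all 10 IRI animals on both sides, which alone pulls the slope below 0, it was -0.085 for IPC, -0.211 for IPO and -0.223 for IPC+IPO over the 35 genes (permutation p = 0.297, 0.04 and 0.04). The permuted slopes do not hold that pull, so these p values cannot tell a reversal from it. Over all genes with split IRI animals the slope was 0.118, 0.041 and 0.025 (permutation p = 0.307, 0.832 and 0.861).

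**Figure D4:**
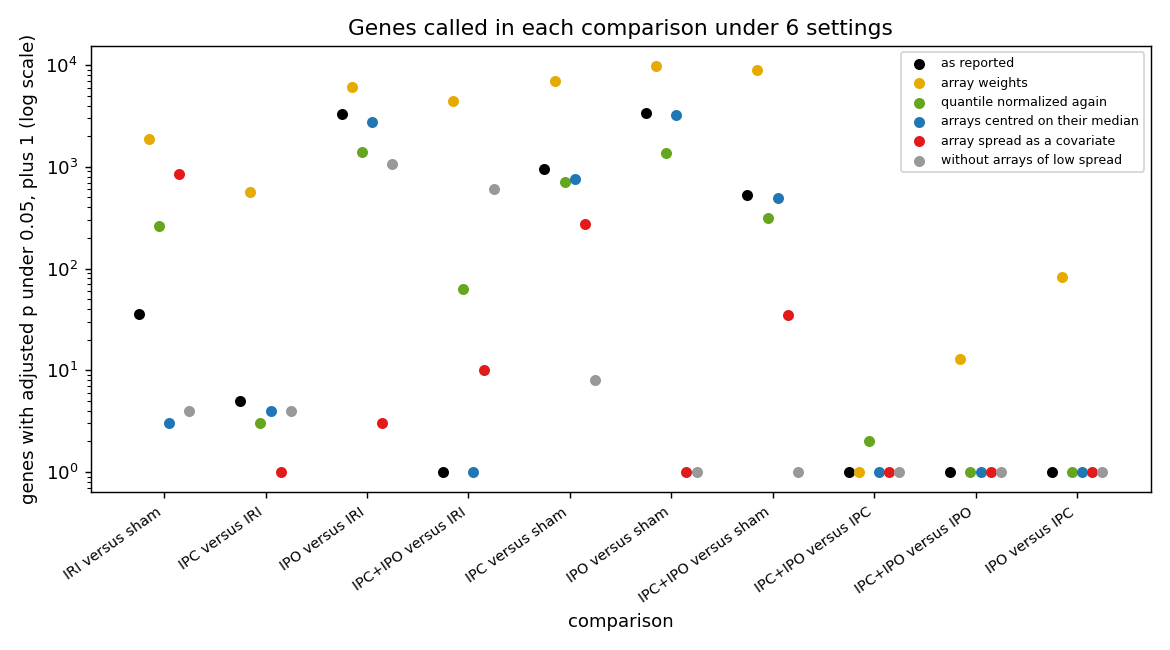
Number of genes with an adjusted p under 0.05, plus 1, on a log scale (vertical axis) in each comparison (horizontal axis) as reported and under 5 alternatives. The comparison of IPO with IRI has 3307 genes as reported and 2 with array spread as a covariate, and that of IRI with sham 35 and 854.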

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

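The tests of cell make-up, of the metallothionein genes and of the clock genes were chosen after the results they weigh had been seen, as was array spread as a covariate.

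Most of the 3307 genes called between IPO and IRI went in the direction of array spread, which may account for part of their size. Of these genes, 97.5% differed in the direction of their slope on spread within the sham, IPC and IPC+IPO groups, 28 arrays outside the comparison, as did 88.5% of all genes. Over all genes the slope of observed on predicted differences was 1.11 (Pearson r = 0.808). Over the called genes it was 1.74, with a median predicted size of 0.22 against 0.42 observed. With spread as a covariate the median size of their differences went from 0.42 to 0.16 on the log2 scale and the median SE from 0.13 to 0.10, so the calls ended because the differences shrank; 100% kept their sign. Mt1 and Mt2A were the 2 genes that still passed, at -1.41 and -1.72 with the covariate (mean -1.57, limma p adjusted over all genes 0.0188 and 0.0216). They were singled out by that fit, so they are no separate test of spread as the whole cause. The marker lists cannot tell a change in cell make-up apart from spread. Of the 8 lists of other cells 4 had a median above 0, and none was called with an estimated correlation. Such a change can move these lists in either direction, so the signs of their medians do not decide it. A cause of the spread itself, be it RNA quality, hybridization or the intervention, stays open and untested.

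With spread as a covariate, IRI against sham had the larger count of 854 genes. Among 100 splits of the 18 arrays the real split alone reached that count (1 of 100, highest other 286). This is the smallest share that 100 splits can give. The covariate was chosen after the data were seen, so chance is not excluded by this share. The median residual SD was 0.267 without and 0.212 with the covariate. In a fit of the 18 arrays alone the covariate moved the count from 0 to 49, all 49 among the 854, and 100% of the 854 had the same sign there; in the fit of all arrays it moved the count from 35. How much of the larger count rests on slopes taken from the other 3 groups cannot be told apart from what rests on the larger number of arrays, since the fit of all arrays changes both. The effect of ischemia, which the design names, stays open as untested beyond this.

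Of the 15 clock genes measured, a list fixed before the data were examined, 4 rose and 2 fell in IPO against IRI, and 10 passed adjusted over the list alone. Of these 10, 6 stayed past that threshold with the same sign with array spread as a covariate (Bmal1 at 0.98 ± 0.35, Cry1 at 0.57 ± 0.14, Dbp at -1.53 ± 0.55, Nr1d1 at -1.10 ± 0.39, Per3 and Tef), and 0 of the 15 passed over all genes. The slopes on spread in the 3 other groups predict a rise of Dbp, Nr1d1, Per3 and Tef (0.11, 0.25, 0.19 and 0.08), so array spread is argued against as the whole cause. Adjusted over the list alone, 2 clock genes rose and 0 fell in IPC against IRI, and 0 passed in IPC+IPO against IRI. With slopes on spread removed, the mean of Bmal1, Clock, Npas2, Nfil3 and Cry1 was higher by 0.56 ± 0.12 and that of Dbp, Tef, Nr1d1, Nr1d2 and the 3 Per genes was at -0.77 ± 0.20, but these sets were formed after their values were seen, so they say nothing about a cause. In IPC, without postconditioning, the same means differed from IRI by 0.44 ± 0.19 and -0.42 ± 0.21 (permutation p adjusted 0.0842 and 0.13). As deposited the first was at 0.6 ± 0.21 there (adjusted 0.0439). In IPC+IPO, which had the cycles, the means differed by 0.13 ± 0.21 and -0.21 ± 0.24 (adjusted 0.716 and 0.613). IPO and IPC+IPO were not compared directly for these means, so the values do not show whether the shift followed postconditioning. Sampling at another time of day and an effect of postconditioning cannot be told apart, as the labels give no hour of sampling, and both stay open.

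Some animals stood apart in single values: the gap from the highest or lowest animal to its nearest neighbour, as a share of the group's range, was above Dixon's critical value at 95%. Over the 324 genes that the naming rules picked, together with list means and array summaries, 85 of 1027 groups of values had such a value. After that count was seen, single values were kept for the 110 genes these texts name, where 49 of 512 groups had one; in simulated normal values 4.9% of groups of 8 and 5% of groups of 10 did. IPO animal 30 was lowest of its group in array spread (1.749), in Ass1 (11.73), Ifi44l (4.65), Mgat2 (8.4), Nqo2 (7.91) and C5h1orf122 (7.83), and in the mean log2 level of the Kupffer cell and macrophage (6.73), ribosomal protein (10.41), interferon-stimulated (5.83), oxidative stress (8.64) and complex I lists (9.2), and highest in Per3 (5.44). IRI animal 7 was lowest in Dnajb4 (5.16), Glrx (6.2), Hspd1 (7.8), Rig1 (4.96), Zmpste24 (5.38) and the mean of the growth and regeneration list (5.77), and highest in Elane (6.33) and Hk2 (5.74). IRI animal 1 was lowest in Gpx1 (11.54), Hbb (11.36) and Rpl36 (10.57) and highest in Fga (12.45), and IRI animal 5 was highest in Junb (9.97). IPO animal 22 was highest in Ubd (7.45) and the mean of the apoptosis list (7) and lowest in Elane (5.03), IPO animal 24 lowest in Clock (6.49) and IPO animal 25 lowest in Fgb (11.85), Calr (10.53), Hspa5 (10.66) and Hsp90b1 (10.35). IPC+IPO animal 37 was lowest in Fdps (9.23) and Nfil3 (6.85) and highest in H4c14 (8.61), and animal 38 lowest in Pdgfra (5.83), Eno1 (8.88), Mgat2 (7.49), Nqo2 (7.32) and the mean of hepatocyte markers (11.67) and highest in that of lymphocyte markers (5.5). IPC animal 11 was highest in Abcc4 (7.54) and animal 18 in the mean of mesothelial and adipose markers (7.13). Sham animal 48 was highest in Cxcl1 (8.08) and the mean of cytokines and chemokines (5.82), sham animal 47 was lowest in Bnip3 (7.82), and sham animal 43 lowest in the means of lymphocyte (4.91) and neutrophil markers (4.76).

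The 13905 probe sets with no or several gene symbols, which no gene count used, were tested in the same way: 33 passed in IRI against sham, 4 in IPC against IRI and 1532 in IPO against IRI.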

How the results depend on the processing

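Array spread as a covariate, the fits without the 14 arrays of lowest spread and the removal of slopes on spread were chosen after the data were seen; the cause of a change was not tested unless one is given. Counts are in the order IRI with sham, then IPC, IPO and IPC+IPO with IRI, then IPC, IPO and IPC+IPO with sham, and only those that moved by over 1.5 times are given. As reported they were 35, 4, 3307, 0, 955, 3364 and 525.

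Array weights gave 1894, 568, 6098, 4484, 7051, 9749 and 9007 genes, and 12 for IPC+IPO with IPO, 82 for IPO with IPC and 189 for the interaction. Spread as a covariate gave 854, 0, 2, 9, 275, 0 and 34, and fits without the arrays of lowest spread, with fewer arrays, 3 for IRI with sham, 1077 and 601 for IPO and IPC+IPO with IRI, 7, 0 and 0 against sham and 1 for the interaction. Renewed quantile normalization gave 259, 2, 1383 and 62 for the comparisons of IRI with sham and of the interventions with IRI, 1365 and 313 for IPO and IPC+IPO with sham and 1 for IPC+IPO with IPC. Centred arrays gave 2 for IRI with sham, leaving out the dimmest genes 57, and all probe sets 78, and 2 for IPC+IPO with IRI. Fits of the groups compared alone gave 0 for IRI with sham, 0 for IPC with IRI, 5455 for IPO with sham and 12 for IPC+IPO with sham, and the trended, robust model 0 for IPC with IRI. Stricter by construction, a 1.5-fold minimum left 20, 0, 688, 519, 1065 and 306 genes where any had passed, and an adjusted p under 0.01 left 2, 0, 41, 142, 697 and 30.

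Leaving out 1 array at a time gave 1 to 324, 0 to 252, 395 to 5345, 0 to 1705, 293 to 2391, 1789 to 5572 and 49 to 2432 genes, 0 to 0 for IPC+IPO with IPC, 0 to 2 for IPC+IPO with IPO, 0 to 2 for IPO with IPC and 0 to 8 for the interaction. The counts of called lists, 8, 21, 11 and 15 in the main comparisons, stayed between 7 and 10, 20 and 23, 9 and 16, and 13 and 16. They were 0 in each with an estimated correlation and 1, 0, 1 and 0 with fry. For IPO and IPC+IPO with IRI they were 6 and 6 without the dimmest genes and 7 and 9 with spread as a covariate. With the covariate and an estimated correlation together camera called no list in the main comparisons (smallest adjusted p = 0.326, 0.282, 0.149 and 0.311).

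The correlation of the IPC and IPO differences, 0.685, was 0.463 with IRI animals split by low and high number and 0.383 with slopes on spread removed. The slopes on the change from sham to IRI had no value as planned. With the low and high split they were 0.065, -0.137 and -0.007 for IPC, IPO and IPC+IPO (permutation p = 0.564, 0.178 and 0.95), over 0 and 407 genes, without the dimmest genes -0.087, -0.195 and -0.217 (p = 0.287, 0.01 and 0.03), over 10 genes called in 1 part of the IRI animals and 0 in the other, and with slopes on spread removed -0.143, -0.264 and -0.248 (p = 0.069, 0.01 and 0.03), over 1148 and 27 genes.

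Signs turned in a few cases. Without the arrays of lowest spread the IRI difference from sham was -0.177 for Tm7sf2, -0.082 for Atp5mc2, -0.142 for Marchf2 and -0.132 for Ftl1, and the IPC difference from sham 0.314 for Rpph1, where 2 sham arrays were left. With spread as a covariate the list median was 0.014 for neutrophil markers (IPC with IRI), and in IPO with IRI -0.013 for gluconeogenesis, -0.008 for lipid synthesis, -0.01 for drug and bile acid metabolism, -0.043 for Kupffer cell markers and -0.138 for complex I, which was -0.135 after quantile normalization; it was -0.001 for hepatocyte markers (IPC+IPO with IRI). Over the analyses fixed before the values were seen, of 4255 values of genes 3879 kept direction and call, 130 lost the call, 244 gained it, 0 reversed and 2 uncalled ones changed sign, and of 616 list values 543 kept both, 40 lost, 12 gained, 1 reversed and 20 changed sign. Over those chosen later, of 1076 gene values 749 kept both, 233 lost, 56 gained, 5 reversed and 33 changed sign, and of 124 list values 74 kept both, 15 lost, 5 gained, 7 reversed and 23 changed sign. Values called in neither fit and of the same sign count as kept here, so these numbers do not measure how often calls held. Signal over background was not measured, so small differences of dim genes were not separated from background.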

Other observations

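The fits with array spread as a covariate were chosen after the data were seen, and so were the genes they single out here.

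Of 3 further lists in IPO against IRI camera called none, and members went both ways in each, in a comparison that called 3307 of 14506 genes. Of 19 genes of the unfolded protein and integrated stress response 4 rose, among them the endoplasmic reticulum chaperone genes Hspa5, Calr and Hsp90b1 by 0.52 ± 0.15 (SE), 0.51 ± 0.14 and 0.42 ± 0.13 on the log2 scale, and Sdf2l1 fell by 0.62 ± 0.19; 6 rose and 1 fell adjusted over the list alone (median 0.23, camera adjusted p = 0.055). Of 26 hypoxia-inducible genes 2 rose, the glycolytic Eno1 by 0.72 ± 0.21 and P4ha2 by 0.33 ± 0.11, and 2 fell, Hk2 by 0.42 ± 0.10 and Bnip3, a mitophagy receptor gene, by 0.66 ± 0.18, also adjusted over the list alone (median 0.01, camera adjusted p = 0.886). Of 18 glucocorticoid-induced genes 5 rose, among them Tat by 0.70 ± 0.20 and Pdk4 by 1.01 ± 0.33, and Mt2A fell; 6 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.146). With array spread as a covariate 0 genes of the first 2 lists passed, and of the third Mt2A alone.

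In IPC+IPO against IRI with spread as a covariate, 9 genes passed. Kdsr and Cers2, enzymes of sphingolipid synthesis, were higher by 0.57 ± 0.12 and 0.64 ± 0.14, Glrx by 0.66 ± 0.14, Zmpste24 by 0.56 ± 0.11, Nqo2 by 0.44 ± 0.09 and Dnajc8 by 0.39 ± 0.08. Mgat2, an enzyme of N-glycan synthesis, fell by 0.60 ± 0.10, C5h1orf122 by 0.50 ± 0.11 and Stk25 by 0.38 ± 0.08. The adjusted p was 0.0495 for each but Mgat2, for which it was 0.00909. In IRI against sham the same covariate left 17 of 67 ribosomal protein genes higher, where 4 were without it.

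Each count was compared with those of 100 splits of the arrays compared into groups of the same sizes, the real split included. The real count of 35 genes for IRI with sham was matched by 3 of 100 splits (highest other 3989), the 4 genes for IPC with IRI by 2 (highest other 24) and the 3307 genes for IPO with IRI by 2 (highest other 4695). Against sham, 955, 3364 and 525 genes were matched by 1 split each, the real one (highest other 1, 2231 and 387). All 6 counts passed the bar set for each, fewer than 5 of 100 splits, which was not adjusted for the number of counts compared. Chance is not excluded by this, since single other splits gave more genes in the first 3 comparisons. The counts of 0 for IPC+IPO with IRI, between the intervention groups and for the interaction are matched by all 100 of 100 splits whatever the data, so the splits say nothing about chance there (limma gave 3118, 235, 482, 589 and 2942 genes at an unadjusted p under 0.05; highest other 4446 for IPC+IPO with IRI, 0, 2 and 1 between intervention groups and 0 for the interaction). Splits with such high counts, for IRI with sham and for IPO and IPC+IPO with IRI, point to a structure of the arrays that the groups do not explain. For called lists, the 21 of IPC with IRI were matched by 2 splits (highest other 21, as many as the real split), which passes the same bar narrowly. The 8, 11 and 15 of IRI with sham, IPO with IRI and IPC+IPO with IRI were matched by 32, 23 and 11 (highest other 15, 21 and 20), so chance cannot be excluded. The other splits called a median of 6 lists for IRI with sham and 8 for each intervention with IRI. Of them 93, 95, 99 and 98 called at least 1 list for IRI with sham, then IPC, IPO and IPC+IPO with IRI. Camera at the preset correlation thus often called lists here without a real grouping.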
